A study of Sus scrofa with 6 samples.

How the data were processed

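Single-nucleus RNA sequencing was run on 6 libraries of pig (Sus scrofa) kidney biopsy tissue. Per the labels, the biopsies were stored in 1 of 3 ways: snap-frozen in liquid nitrogen (SnapFrozen, 3 libraries), in RNAlater, a salt solution that stabilises RNA (RNAlater, 2 libraries), or in CellCover, a commercial preservation solution (CellCover, 1 library). Nuclei were released with a Nuclei PURE lysis buffer, passed through strainers of 30 and 5 micrometres with a red blood cell lysis step between, and loaded for about 6000 or 10000 nuclei per library. Libraries were made with the 10x Chromium 3' chemistry, version 3.1, and sequenced on a NovaSeq 6000 with 150-base paired reads, about 200 M per library. Which library had which loading target, and from which animals the biopsies came, is not given in the sources used here. Replicate numbers follow the order of the libraries in the series and pair nothing across groups.

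The deposited matrices hold raw UMI counts per gene and barcode, made by the authors with Cell Ranger 6.1.1 on genome build Sscrofa11.1, per the submitters' processing notes. The annotation release and whether intronic reads were counted are not given in the sources used here. Each matrix holds the barcodes that Cell Ranger called as nuclei, and the lowest total of any barcode was 500 UMIs. The 6 matrices share 31908 features, of which 16554 carried a symbol in the files and 15354 only an Ensembl ID; a table of gene names gave a symbol to 822 of the latter. The 6 libraries held 57179 barcodes and 362242556 UMIs. Pairs of libraries were compared gene by gene, and no pair agreed within sampling noise. The chi-square per degree of freedom was 138 to 156 within SnapFrozen, 125 within RNAlater and 112 to 255 between groups. The lowest value was that of SnapFrozen replicate 2 with RNAlater replicate 1. This measure grows with the number of UMIs, so it does not rank likeness across pairs of unlike depth. The Pearson correlation of log2 CPM was 0.976 for that pair and 0.979 to 0.985 within groups. It was 0.982 for SnapFrozen replicate 3 with RNAlater replicate 1. By the correlation, libraries stored alike were not always closer than libraries stored differently.

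Nuclei were kept with at least 200 genes and at most 10% mitochondrially encoded UMIs, which removed 48 barcodes. Throughout, mitochondrially encoded UMIs and genes are those of 13 protein-coding genes. Other transcripts of the mitochondrial genome were not counted among them. Barcodes with the highest doublet scores were then removed at 0.8% per 1000 nuclei of the library, 4664 in all, which left 52467 nuclei. The score was the share of simulated doublets, 2 per nucleus, among nearest neighbours in principal components. Counts were scaled to 10000 per nucleus and log-transformed, and 2000 variable genes ranked within libraries gave 30 principal components. Libraries were joined with an implementation of the Harmony algorithm written for this work, and nuclei were clustered with leidenalg 0.10.2 and igraph 0.11.9 at resolution 1 on 20 neighbours. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3 were used, and matplotlib 3.10.9 drew the plots.

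The clusters numbered 31. A cluster took the name of a cell type when at least 3 markers of that type were 2-fold above the other clusters, its mean marker score led the runner-up by 0.5, and its 10 leading genes held no more markers of another type. Leading genes had to be detected in 10% of the cluster's nuclei, and 5 CPM were added before the log2 values behind the marker scores were taken. A cluster with few UMIs per nucleus and no marker of its best type among the leading genes also stayed unnamed. This rule was set after the clusters had been seen, from marker lists for 20 cell types fixed before. It named 22 clusters in 13 classes and left 9 unnamed. Classes are called "like" a cell type, since the names rest on marker RNA alone.

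For differential expression, UMI counts were summed per library over all retained nuclei or over the nuclei of a class, since nuclei are not replicates. Libraries with under 30 nuclei of a class were left out of its fit. The sums were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. All 6 libraries shared 1 estimate of the spread, with 3 residual degrees of freedom from the SnapFrozen and RNAlater libraries. The CellCover library has no replicate and was assumed to vary like the others, so its contrasts rest on that library alone. Nothing states that replicates came from separate animals, so p-values measure the spread between these libraries, which may be partly technical. The storage by class interaction was tested with the library as a block. Class shares were tested with edgeR on nuclei per class with the library total as scaling, beside exact two-sided permutation tests, whose smallest possible p with 3 against 2 libraries is 0.2. Shares of single libraries carry 95% Wilson intervals, which cover counting error only.

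The comparisons, 22 gene lists, 20 marker lists, the rule for named genes and 78 alternatives were fixed before the data were examined. The lists were immediate early genes, heat shock chaperones, hypoxia and glycolysis, osmotic response, unfolded protein response, p53 and apoptosis, oxidative stress, inflammation, tubular injury, cold response and splicing, mitochondrially encoded genes, nuclear-encoded oxidative phosphorylation, fatty acid oxidation, gluconeogenesis, proximal tubule transport, distal nephron transport, haemoglobin and plasma proteins, extracellular matrix, swine leukocyte antigens, sex-linked genes, ribosomal proteins and nuclear-retained RNA. No member of the last list had its symbol in the files, so 21 lists were tested. The tests were camera (limma 3.58.1) with an inter-gene correlation of 0.01, camera with the correlation estimated, and fry, each adjusted over lists; marker lists were adjusted among themselves. Marker list tests within a class use lists that also helped to name its clusters.

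Gene positions are on Sscrofa11.1 and come from a RefSeq gene table of that assembly. Named genes followed a rule: among genes with a symbol that passed the threshold, reached 10 CPM in the higher group and did not overlap between groups, the 10 largest rises and falls in the 3 main contrasts and the first 3 of each direction in the others. Where none passed, the 5 highest and 5 lowest fold changes of genes at 10 CPM without overlap were given as values (the first 3 in the other contrasts). Each list gave up to 4 members that passed, or up to 2 of the highest CPM. FOS, JUN, HSPA8, LRP2 and UMOD were named in any case; MALAT1 and HAVCR1, also in the rule, had no feature with their symbol. Not every gene that the rule selects is printed. Outside the rule, and chosen after their values were seen, are the genes known only by Ensembl ID, a U4 spliceosomal RNA copy, COX1 and CYTB in the thick ascending limb-like class, NRXN3 in the endothelial-like class, KDM5D, and the genes named for the fibroblast-like class and the other classes of the closing section.

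Alternatives were DESeq2 1.42.0 in place of edgeR, DESeq2 size factors in edgeR, no low-count filter, a filter of 10 CPM in 2 libraries, sums thinned to the smallest, only the 2 groups compared, every deposited barcode, a stricter nucleus filter (500 genes, 5% mitochondrial), doublets kept, libraries not joined, resolutions 0.5 and 2, classes by a marker score per nucleus, mitochondrially encoded genes left out, and each library left out in turn. Alternatives chosen after seeing the data were unnamed clusters left out, the class contrasts of CellCover beyond the proximal tubule-like class, the tests on the other 10 classes, the other settings of the marker lists and the list tests between classes.

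The steps were tested on simulated data. For the gene tests, each gene was drawn independently with the trended spread. Shifts shared by many genes, such as those from shares of cell types, were not simulated, so rates in the real data can differ. In each simulation 200 genes were changed at once, 50 each by 2-, 4-, 8- and 16-fold. So many changed genes ease the adjusted threshold, so recovery can be lower where few genes change. Of the 50 genes changed 4-fold, edgeR recovered 62% for RNAlater and 36% for CellCover in sums like those of all nuclei. Of the 50 changed 2-fold it recovered 2% and 6%. It also called 6 unchanged genes among 22560 tested and 2 among 22504. In sums like the proximal tubule-like class it recovered 62% of 4-fold changes for RNAlater and 26% for CellCover, and called 9 unchanged genes among 19055 and 2 among 19069. The share test recovered 87.3% of 4-fold changes and called 2.4% of unchanged classes. Clustering of 2400 simulated nuclei recovered their 6 classes (adjusted Rand index 1 with joining, 0.301 without). The doublet score separated simulated doublets of different classes from single nuclei with an area under the curve of 0.998. Doublets within a class were not scored. This simulation was smaller and simpler than the data and used fewer Harmony clusters, so it checks the code and not the accuracy on the real nuclei.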

Results

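RNA from single nuclei was counted in pig kidney biopsies stored by snap freezing, in RNAlater or in CellCover, within a series on a kidney tissue workflow for multi-omics and histology. The 3 SnapFrozen libraries held 61796611, 34415254 and 107784474 UMIs, the 2 RNAlater libraries 51379960 and 70273301, and the CellCover library 36592956. After filtering, 12533, 6763 and 10611 nuclei were retained from the SnapFrozen libraries, 8083 and 7533 from RNAlater, and 6944 from CellCover. The comparisons ask how the profile of kidney nuclei differs with the way the biopsy was stored, and SnapFrozen was the reference. Expression is given as CPM, counts scaled to the same total in each library, means carry the SD between libraries, and log2 fold changes carry the SE of the fit. Gene positions are on Sscrofa11.1.

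Transcripts of 13 mitochondrially encoded protein genes took a larger share of the UMIs in both RNAlater libraries than in any SnapFrozen library. Such RNA lies outside the nucleus in an intact cell. The mean share was 0.502% ± 0.0863 (SD, n = 2) in RNAlater, 0.126% ± 0.0269 (SD, n = 3) in SnapFrozen and 0.458% in CellCover. The 3 SnapFrozen libraries lay between 0.106% and 0.157% and the 2 RNAlater libraries between 0.441% and 0.563%. Nuclei with under 1000 UMIs made up 13.8% ± 1.32 of RNAlater nuclei, 6.67% ± 3.04 of SnapFrozen nuclei and 12.3% of CellCover nuclei. Both differences separated the groups, but an exact permutation test of 3 against 2 libraries cannot go below the p of 0.2 that each gave. Nuclei held a median of 2664 ± 338 genes in RNAlater, 2233 ± 479 in SnapFrozen and 1889.5 in CellCover (exact permutation p = 0.4 for RNAlater). That difference of 431 genes was 252.5 without SnapFrozen replicate 1, 703.5 without SnapFrozen replicate 3, 670.3 without RNAlater replicate 1 and 192 without RNAlater replicate 2. After thinning each nucleus to 1000 UMIs the medians were 736 ± 22.6, 724 ± 14.8 and 728 genes. Ribosomal protein transcripts took 0.521% ± 0.167 of UMIs in RNAlater, 0.432% ± 0.0421 in SnapFrozen and 0.238% in CellCover.

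All 13 nucleus classes were found under each way of storage, and proximal tubule-like nuclei, the cells that reclaim most of the filtrate, were the largest named class in each library. They made up 37.1% ± 13.8 (SD, n = 3) of SnapFrozen nuclei, 35.7% ± 4.95 (SD, n = 2) of RNAlater nuclei and 19.1% of CellCover nuclei. Endothelial-like nuclei made up 7.56% ± 0.703 in RNAlater and 14.2% ± 5.16 in SnapFrozen. Acid-base regulating intercalated cell-like nuclei made up 2.72% ± 1.74 and 5.66% ± 0.946, and connecting tubule-like nuclei 2.79% ± 1.32 and 5.55% ± 1.97. In CellCover the thick ascending limb-like class, which reabsorbs salt without water, took 17.2%, against 5.38% ± 4.03 in SnapFrozen. Filtration-barrier podocyte-like nuclei took 0.475% there against 1.64% ± 0.480, and distal convoluted tubule-like nuclei 0.965% against 2.96% ± 1.11.

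None of the 13 class shares passed the edgeR test in either contrast. The lowest adjusted p was 0.383 for RNAlater, shared by the intercalated (log2 −1.06 ± 0.54), connecting tubule (−0.99 ± 0.53) and endothelial (−0.91 ± 0.51) classes, each lower in both RNAlater libraries than in any SnapFrozen library (exact permutation p = 0.2). T and NK lymphocyte-like nuclei were higher in both, with 1.72% ± 0.421 against 1.21% ± 0.138 (log2 0.51 ± 0.49, adjusted p = 0.692, exact permutation p = 0.2). For CellCover it was 0.2003, shared by the podocyte (−1.78 ± 0.85), thick ascending limb (1.68 ± 0.68) and distal convoluted tubule (−1.61 ± 0.73) classes. Of the single classes, 0 of 13 had an unadjusted p under 0.05 for RNAlater and 3 of 13 for CellCover. Without SnapFrozen replicate 2 the thick ascending limb share passed for CellCover (log2 2.49, adjusted p = 0.018), the only such call when single libraries were left out. Clusters without a name held 8.77%, 12.2% and 21.9% of nuclei in SnapFrozen, 24.97% and 26.5% in RNAlater and 23.9% in CellCover. Unnamed clusters 7 and 11, of 3138 and 1435 nuclei, scored highest for proximal tubule markers but had under 3 markers at 2-fold. In the order above they held 333, 127, 859, 843, 611 and 365 nuclei, and 194, 77, 115, 250, 342 and 457 nuclei. The proximal tubule-like shares, and their difference in CellCover, thus depend in part on the naming rule.

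**Figure D1:**
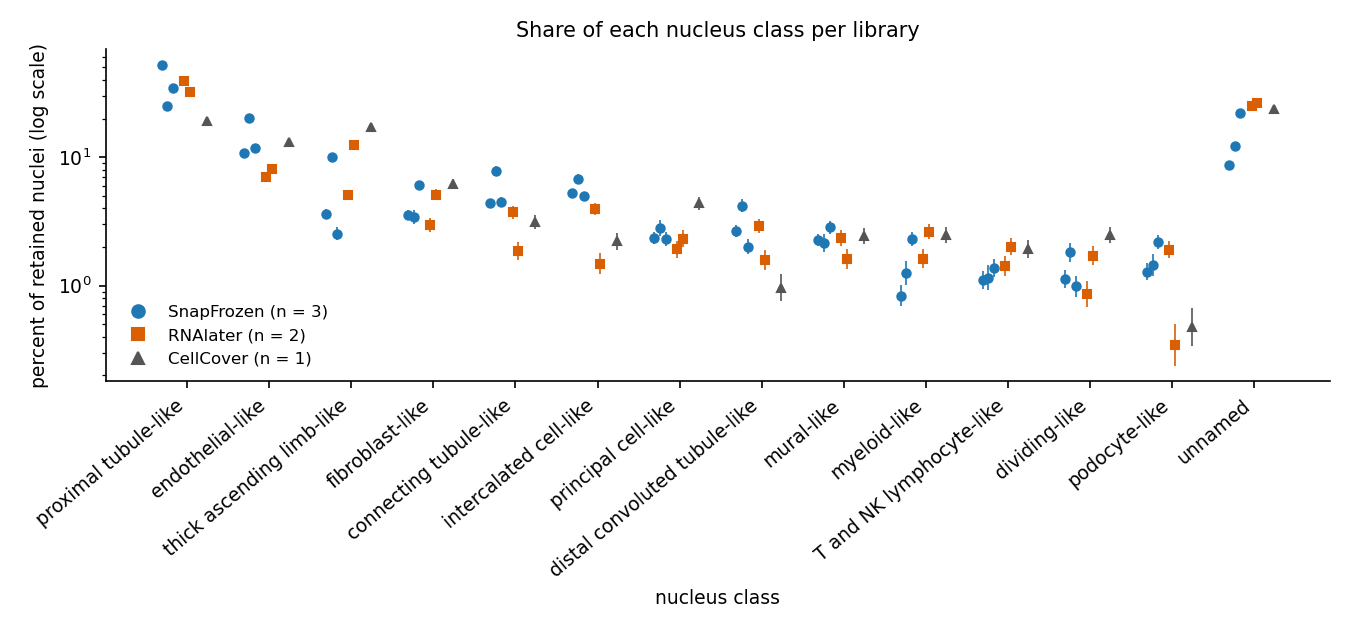
Percent of retained nuclei in each class (y axis, log scale) per library, with circles for SnapFrozen, squares for RNAlater and triangles for CellCover; bars are 95% Wilson intervals for counting error. Thick ascending limb-like nuclei made up 17.2% in CellCover and a mean of 5.38% in SnapFrozen, and unnamed nuclei between 8.77% and 26.5%.

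In the RNAlater libraries 2 transcripts of the mitochondrial genome rose over all nuclei, both subunits of respiratory complex I. ND6 (ENSSSCG00000018092, MT 14739 to 15266) rose from 11.4 ± 0.927 CPM (SD, n = 3) to 60.5 ± 1.51 CPM (n = 2), a log2 fold change of 2.40 ± 0.21 with an edgeR adjusted p of 0.0422. ND3 (ENSSSCG00000018084, MT 10653 to 10998) rose from 25.2 ± 5.91 to 205 ± 71.8 CPM (log2 3.02 ± 0.30, adjusted p = 0.0453). The other call was a gene known only as ENSSSCG00000038719, which rose from 3.10 ± 1.88 to 236 ± 81.3 CPM (log2 6.24 ± 0.60, adjusted p = 0.0453); it is a leading gene of an unnamed cluster. For all 3 genes, both RNAlater libraries lay above every SnapFrozen library. No gene of cell identity named here passed: LRP2, the endocytic receptor of the proximal tubule (15: 75565299 to 75754604), had 1971 ± 184 CPM in RNAlater and 1878 ± 590.5 in SnapFrozen, a log2 fold change of 0.07 ± 0.39 (adjusted p = 0.979). UMOD, the urinary protein of the thick ascending limb (3: 25473048 to 25492286), had 589.5 ± 30.4 and 344 ± 201 CPM.

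In this contrast edgeR called 3 of 23159 genes, all higher, with 2125 at an unadjusted p under 0.05, and DESeq2 called 233. Groups did not overlap for 25.9% of genes, where chance gives 20%. The count was 1 without SnapFrozen replicate 1, 0 without SnapFrozen replicate 2 and 4 without SnapFrozen replicate 3. The number of calls thus depended on which libraries were in the fit. Log2 fold changes stayed at 2.37 to 2.47 for ND6 and 2.62 to 3.35 for ND3 whichever library was left out. That of ENSSSCG00000038719 stayed at 5.82 to 6.63. With a library left out, ND3 had an adjusted p of up to 0.203 and ND6 of up to 0.153.

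Among the gene lists, the mitochondrially encoded genes stood out in RNAlater. All 13 were higher, by a median log2 of 1.88; 2 passed over all genes tested and 13 adjusted over the list alone (camera adjusted p = 6.11e-26). The adjusted p = 0.257 with an estimated correlation, and fry gave 0.0425. This goes with the higher mitochondrial share given above.

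Another 6 lists passed camera in RNAlater, with no member past the threshold over all genes. Cold response and splicing genes were lower in 21 of 22 by a median log2 of −0.29, with 0 adjusted over the list alone (camera adjusted p = 0.000859, adjusted p = 0.849 with an estimated correlation). The RNA helicase DDX5 (12: 14571712 to 14580740) had 229 ± 39.4 CPM against 424 ± 57.0, and its paralog DDX17 (5: 9485792 to 9505157) 399 ± 45.2 against 405 ± 31.1. Tubular injury genes were higher in 15 of 17 by a median of 0.61, with 0 adjusted over the list alone (camera adjusted p = 0.00239, adjusted p = 0.849 with an estimated correlation). Among the abundant members DCDC2 had a log2 of 0.56 ± 0.64 and the adhesion protein CDH2 −0.12 ± 0.37. Ribosomal protein genes were higher in 41 of 66 by a median of 0.14, with 0 adjusted over the list alone (camera adjusted p = 0.00336, adjusted p = 0.849 with an estimated correlation). RPS2 (3: 39996179 to 40003110) had a log2 of 0.45 ± 0.32 and RPL7A (1: 272961421 to 272965636) −0.09 ± 0.36. Immediate early genes, transcribed within minutes of stress, were lower in 20 of 30 by a median of −0.30, with 1 adjusted over the list alone (camera adjusted p = 0.00812, adjusted p = 0.849 with an estimated correlation). FOS had 18.4 ± 13.3 CPM against 28.8 ± 6.75, JUN 59.7 ± 9.62 against 58.4 ± 26.3 and ATF3 47.0 ± 14.4 against 54.2 ± 25.4. The list of swine leukocyte antigens, the antigen-presenting molecules of the pig, held 17 genes, of which only 6 had their symbol in the files. SLA-1, SLA-2, SLA-3 and SLA-DRA were missing, and CD74 and B2M were among the 6. All 6 were higher, by a median of 0.49, with 0 adjusted over the list alone (camera adjusted p = 0.0128, adjusted p = 0.849 with an estimated correlation). CD74 (2: 151402210 to 151409924) had 251.5 ± 66.1 CPM against 156 ± 29.7, and B2M a log2 of 0.22 ± 0.36. The 3 sex-linked genes passed as well (camera adjusted p = 0.0312, adjusted p = 0.849 with an estimated correlation, 3 adjusted over the list alone), all from RNAlater replicate 2, where ZFY, EIF1AY (Y: 9687350 to 9704489) and KDM5D reached 149.7, 44.1 and 25.4 CPM; no other library exceeded 0.116 CPM. RNAlater replicate 2 thus holds nuclei of a male animal, which no other library shows, so animal and storage are not separated in the RNAlater contrasts.

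Single libraries ended each of these 6 calls. The adjusted p without SnapFrozen replicate 1 was 0.0632 for the cold response, immediate early, leukocyte antigen and sex-linked lists, and without SnapFrozen replicate 2 it was 0.647 for ribosomal proteins and 0.113 for sex-linked genes. Without SnapFrozen replicate 3 it was 0.102 for leukocyte antigens. Without RNAlater replicate 1 it was 0.0519 for the cold response, 0.958 for ribosomal proteins, 0.214 for leukocyte antigens and 0.529 for immediate early genes, whose direction turned; without RNAlater replicate 2 it was 0.140 for tubular injury. The other 14 lists had a camera adjusted p between 0.166 and 0.770: inflammation, extracellular matrix, oxidative phosphorylation, oxidative stress, hypoxia and glycolysis, proximal and distal transport, haemoglobin and plasma proteins, fatty acid oxidation, unfolded protein response, heat shock, gluconeogenesis, p53 and apoptosis, and osmotic response. Their heat shock member HSPA8 (9: 49982278 to 49986760) had 105.5 ± 13.8 CPM against 129.5 ± 16.9. Proximal tubule transport had a median of −0.20 and a mean of 0.03 while its test pointed up, and the haemoglobin and plasma list (median −0.20) and fatty acid oxidation (median −0.08) had tests pointing up as well; no list that passed, in any contrast, had a median or mean against its test.

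Marker lists of cell types passed camera in RNAlater too. There markers of intercalated cells were lower in 12 of 12 (median log2 −0.88, camera adjusted p = 6.57e-08) and of endothelial cells in 13 of 14 (−0.59, 0.000148), both with an adjusted p = 0.379 with an estimated correlation. Markers of B and plasma cells were higher in 8 of 8 (1.24, 2.12e-07), of myeloid cells in 11 of 11 (0.79, 7.44e-07) and of T and NK lymphocytes in 11 of 12 (0.99, 8.05e-07), and in that order the adjusted p = 0.204, 0.379 and 0.379 with an estimated correlation. Dividing (0.00396, down), connecting tubule (0.00793, down) and thick ascending limb markers (0.0109, up) passed as well, with an adjusted p = 0.393, 0.379 and 0.379 with an estimated correlation. Leaving out SnapFrozen replicate 3 (0.0655, 0.0534 and 0.0708) ended all 3 of these calls. So did RNAlater replicate 1 for dividing markers (0.152) and RNAlater replicate 2 for connecting tubule (0.304) and thick ascending limb markers (0.449). Of these 8 lists, fry called only B and plasma cells (0.0427), and the remaining 12 marker lists had a camera adjusted p between 0.106 and 0.952.

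No gene passed between the single CellCover library and SnapFrozen. Among the highest fold changes were those of NEK10, a kinase of the NIMA family (13: 13751178 to 13931896), with 50.3 CPM against 1.17 ± 0.731 (SD, n = 3), and S100A2 (4: 96073496 to 96076825), with 21.2 against 0.687 ± 0.696. The monocarboxylate transporter SLC5A8 (5: 82973179 to 83088542) had 142 against 6.82 ± 3.05 CPM and the matrix protein TNC (1: 255533235 to 255630381) 43.0 against 3.16 ± 1.44. S100A2 and SLC5A8 are leading genes of a principal cell-like and an unnamed cluster. The lowest fold changes were those of ACSM5 (3: 25393121 to 25422551; 1.37 against 27.9 ± 43.5 CPM), the vitamin D hydroxylase CYP24A1 (17: 55110546 to 55130328; 11.9 against 197.5 ± 246), the haemoglobin gene HBB (9: 4800683 to 4801941; 1.40 against 21.4 ± 27.2), the metallothionein MT1A (6: 18672016 to 18673673; 1.71 against 23.4 ± 15.5) and the cell cycle kinase CDK1 (14: 64233945 to 64255290; 44.1 against 529.6 ± 131). The lowest edgeR adjusted p was 0.0837, reached by SLC5A8 (log2 4.38 ± 0.49). LRP2 had 783 CPM against 1878 ± 590.5 and UMOD 622 against 344 ± 201.

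For CellCover against SnapFrozen edgeR called 0 of 23159 genes, with 2937 at an unadjusted p under 0.05, and DESeq2 called 788. The CellCover value lay outside the SnapFrozen range for 61.4% of genes, where chance gives 50%. The edgeR count became 12 without SnapFrozen replicate 3 (7 higher, 5 lower), 39 without RNAlater replicate 1 (34 and 5) and 30 without RNAlater replicate 2 (27 and 3).

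By camera alone, ribosomal protein and nuclear-encoded oxidative phosphorylation genes were lower in CellCover, and mitochondrially encoded, immediate early, inflammation, extracellular matrix and heat shock genes higher. Ribosomal protein genes were lower in 65 of 66 by a median log2 of −0.90, with 0 past the threshold over all genes and 27 adjusted over the list alone (camera adjusted p = 2.64e-21, adjusted p = 0.412 with an estimated correlation); RPL7A had 126 CPM against 285.5 ± 85.5 and RPS24 131 against 158 ± 41.6. Nuclear-encoded oxidative phosphorylation genes were lower in 41 of 44 by a median of −0.57, with 0 over all genes and 0 adjusted over the list alone (6.99e-11, adjusted p = 0.412 with an estimated correlation), and NDUFA4 had a log2 of −1.02 ± 0.29, against 0.25 ± 0.27 for SDHB. All 13 mitochondrially encoded genes were higher, by a median of 1.77, with 0 over all genes and 12 adjusted over the list alone (4.52e-13, adjusted p = 0.412 with an estimated correlation); COX3 (MT 9800 to 10583) had 1204 CPM against 301 ± 87.3 and COX1 (MT 6511 to 8055) 1234 against 385.5 ± 74.0. Immediate early genes were higher in 27 of 30 by a median of 1.32, with 0 over all genes and 7 adjusted over the list alone (5.88e-12, adjusted p = 0.412 with an estimated correlation). The stress-induced transcription factors ATF3 (9: 130772259 to 130829678), JUN (6: 153686425 to 153687635) and FOS (7: 98449508 to 98451971) had log2 fold changes of 1.84 ± 0.46, 1.54 ± 0.46 and 1.44 ± 0.51. Inflammation genes were higher in 20 of 22 by a median of 0.98, with 0 over all genes and 7 adjusted over the list alone (4.77e-09, adjusted p = 0.412 with an estimated correlation); NFKB1, a subunit of NF-kB (8: 118391010 to 118478927), had 257.6 CPM against 120.5 ± 31.5, and STAT3 331 against 213 ± 70.7. Extracellular matrix genes were higher in 19 of 24 (median 0.53, 4 adjusted over the list alone, 0.000314) and heat shock chaperones in 16 of 20 (median 0.38, 1 adjusted over the list alone, 0.00163), both with an adjusted p = 0.412 with an estimated correlation. COL4A2 had a log2 of 0.28 ± 0.47, THBS1 0.40 ± 0.32, HSP90AA1 1.35 ± 0.29, DNAJB4 0.21 ± 0.32 and HSPA8 0.50 ± 0.28. For these 7 lists fry gave an adjusted p between 0.140 and 0.414.

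Another 5 lists passed camera in CellCover, each with 0 members past the threshold over all genes. Within proximal tubule-like nuclei neither fatty acid oxidation nor proximal tubule transport passed camera, while in endothelial-like nuclei fatty acid oxidation passed as lower. Values here are sums over all nuclei. Proximal tubule-like nuclei made up 19.1% of these in CellCover and a mean of 37.1% in SnapFrozen. Fatty acid oxidation genes were lower in 20 of 22 (median −0.72, 0 adjusted over the list alone, camera adjusted p = 0.00163, adjusted p = 0.580 with an estimated correlation, and camera 0.150 without SnapFrozen replicate 1); ACSL1 had 307.5 CPM against 1309 ± 1494 and PPARGC1A 527 against 690.0 ± 83.5. Proximal tubule transporters were lower in 21 of 30 (median −0.75, 1 adjusted over the list alone, 0.0181, adjusted p = 0.597 with an estimated correlation, and camera 0.112 without SnapFrozen replicate 1); the bicarbonate transporter SLC4A4 (8: 67768955 to 68177213) had a log2 of −1.42 ± 0.57 and the endocytic receptor CUBN −0.56 ± 0.63. Oxidative stress genes were lower in 13 of 19 (median −0.53, 1 adjusted over the list alone, 0.0362, adjusted p = 0.412 with an estimated correlation, and camera 0.0725 without SnapFrozen replicate 1), with the secreted peroxidase GPX3 (16: 71980467 to 71989011) at −1.63 ± 0.54 and catalase, CAT, at −0.71 ± 0.46. Tubular injury genes were higher in 14 of 17 (median 0.58, 0 adjusted over the list alone, 0.0181, adjusted p = 0.489 with an estimated correlation), with DCDC2 at 0.43 ± 0.80 and CDH2 at −1.43 ± 0.51. Unfolded protein response genes were higher in 13 of 17 (median 0.22, 0 adjusted over the list alone, 0.0362, adjusted p = 0.580 with an estimated correlation, and camera 0.129 without SnapFrozen replicate 2 or 0.140 without SnapFrozen replicate 3), with HERPUD1 at −0.15 ± 0.29 and ATF6 at 0.14 ± 0.34. The other 9 lists had a camera adjusted p between 0.0515 and 0.870. Of the marker lists, proximal tubule markers were lower in 17 of 18 (median −1.10, camera adjusted p = 0.000173), intercalated (0.00183) and distal convoluted tubule markers (0.00911) lower, and thick ascending limb (median 1.08, 0.00183), T and NK lymphocyte (0.00207) and mural markers (0.00741) higher, each with an adjusted p = 0.514 with an estimated correlation. Endothelial markers were higher as well (0.0292), but not without SnapFrozen replicate 1 (0.0753) or 3 (0.0882). Their adjusted p = 0.558 with an estimated correlation.

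**Figure D2:**
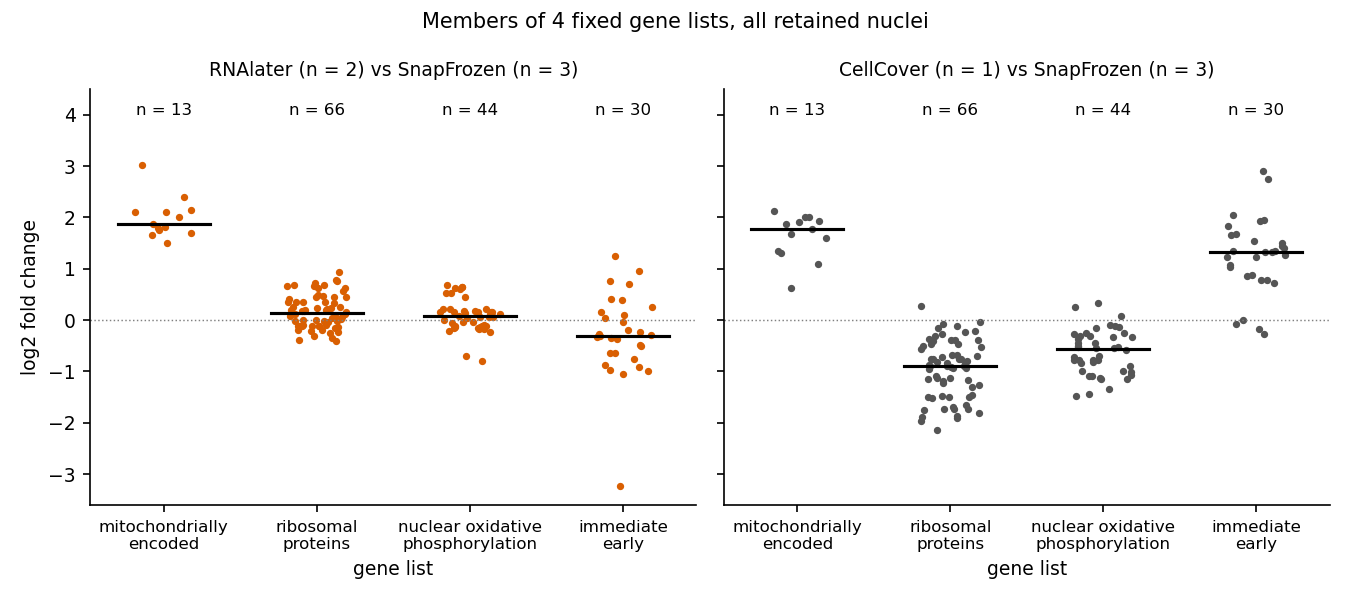
Log2 fold change (y axis) of each member of 4 gene lists over all nuclei, RNAlater against SnapFrozen on the left and CellCover against SnapFrozen on the right; each point is a gene and bars are medians. The 13 mitochondrially encoded genes have medians of 1.88 and 1.77, and the 66 ribosomal protein genes medians of 0.14 and −0.90.

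Set directly against RNAlater, CellCover had 241 CPM of PTPRT, a receptor-type tyrosine phosphatase (17: 44717539 to 45880822), against 23.3 ± 11.9 (SD, n = 2), a log2 fold change of 3.37 ± 0.46. FOS had 78.3 CPM against 18.4 ± 13.3 and JUN 169.7 against 59.7 ± 9.62. MOGAT2 (9: 9937654 to 9951679; 33.7 against 3.07 ± 1.98) and SYNDIG1 (17: 30621622 to 30709387; 31.3 against 3.44 ± 2.52) were the other high values. The low ones were EIF1AY, HBB (1.40 against 41.5 ± 36.6 CPM) and the cytochrome P450 gene CYP2B22 (6: 49158175 to 49173872; 1.18 against 29.9 ± 2.85). None passed: edgeR called 0 of 23159 genes with a lowest adjusted p of 0.248, 1872 had an unadjusted p under 0.05, and DESeq2 called 239. Without RNAlater replicate 1 edgeR called 9.

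Within proximal tubule-like nuclei, 4 mitochondrially encoded transcripts and 1 cytochrome P450 rose in RNAlater. ND3 rose from 12.2 ± 5.18 CPM (SD, n = 3) to 204 ± 97.7 (n = 2; log2 4.06 ± 0.42, edgeR adjusted p = 0.0397). ND6 rose from 4.95 ± 0.736 to 41.1 ± 5.97 (3.05 ± 0.25), the ATP synthase subunit ATP6 (ENSSSCG00000018081, MT 9120 to 9800) from 47.8 ± 12.7 to 357.5 ± 42.8 (2.90 ± 0.26) and the cytochrome c oxidase subunit COX3 (ENSSSCG00000018082) from 123 ± 35.5 to 887 ± 123 (2.85 ± 0.29). CYP2A19, of a family that oxidises drugs and other foreign compounds (ENSSSCG00000002993, 6: 49056579 to 49064111), rose from 29.9 ± 8.97 to 255 ± 8.73 CPM (3.09 ± 0.29, adjusted p = 0.0267); the CellCover library had 161 CPM. ENSSSCG00000038719 (log2 5.41 ± 0.47) and ENSSSCG00000037775 (5.01 ± 0.54) rose too, and both RNAlater libraries exceeded every SnapFrozen library for all 7. LRP2 was level at 3023 ± 115 against 3093 ± 287 CPM, a log2 of −0.03 ± 0.30.

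EdgeR called 7 of 19830 genes, all higher, with 2179 at an unadjusted p under 0.05, DESeq2 called 188, and 27.6% of genes did not overlap. The only call without SnapFrozen replicate 1 was a lower gene, so none of the 7 remained; the count was 0 without SnapFrozen replicates 2 or 3 or RNAlater replicate 2, and 39 (32 higher, 7 lower) without RNAlater replicate 1. With a library left out CYP2A19 had an adjusted p between 0.0193 and 0.147. Of the lists, mitochondrially encoded genes were higher in 13 of 13 by a median log2 of 2.60, 4 over all genes and 13 adjusted over the list alone (camera adjusted p = 2.4e-27; adjusted p = 0.524 with an estimated correlation). Cold response and splicing genes were lower in 17 of 22 (median −0.28, 0 over all genes and 2 adjusted over the list alone, camera adjusted p = 0.000811, adjusted p = 0.776 with an estimated correlation, and camera 0.0652 without RNAlater replicate 1). Immediate early genes were lower in 21 of 26 (median −0.43, 0 over all genes and 1 adjusted over the list alone, 0.00774, adjusted p = 0.776 with an estimated correlation, but camera 0.408 without SnapFrozen replicate 1 and 0.501 without RNAlater replicate 1). Abundant members stayed near 0, with DDX17 at 0.11 ± 0.21, the splicing factor PNISR at 0.15 ± 0.24, JUN at −0.29 ± 0.48 and KLF6 at −0.21 ± 0.52; FOS was at −1.17 ± 0.62 and HSPA8 at −0.50 ± 0.30. The other 18 lists had a camera adjusted p between 0.0718 and 0.997.

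Transcripts of other cell types were higher in these nuclei as well. UMOD had 124 ± 24.8 CPM in RNAlater proximal tubule-like nuclei against 44.3 ± 33.3 (adjusted p = 0.429). Markers of T and NK lymphocytes were higher in 9 of 9 (median log2 1.06, camera adjusted p = 0.00054), of myeloid cells in 10 of 11 (0.93, 0.00154), of the thick ascending limb in 10 of 12 (0.87, 0.00154) and of B and plasma cells in 6 of 6 (1.31, 0.00228). In that order the adjusted p = 0.445, 0.617, 0.471 and 0.471 with an estimated correlation, and fry gave 0.00874 for T and NK lymphocytes. Thin limb markers were higher and proximal tubule markers lower (camera adjusted p = 0.0408 for both; adjusted p = 0.471 and 0.617 with an estimated correlation). The thin limb call ended without SnapFrozen replicate 1 (0.0589) or 3 (0.168) or RNAlater replicate 2 (0.205), and the proximal tubule call without SnapFrozen replicate 1 (0.134) or 3 (0.141), RNAlater replicate 1 (0.359) or the CellCover library (0.0595). The largest of the 3 clusters of this class held 52.2% and 49.3% of it in RNAlater, 47.1% in CellCover and 59.2%, 57.4% and 55.0% in SnapFrozen.

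**Figure D3:**
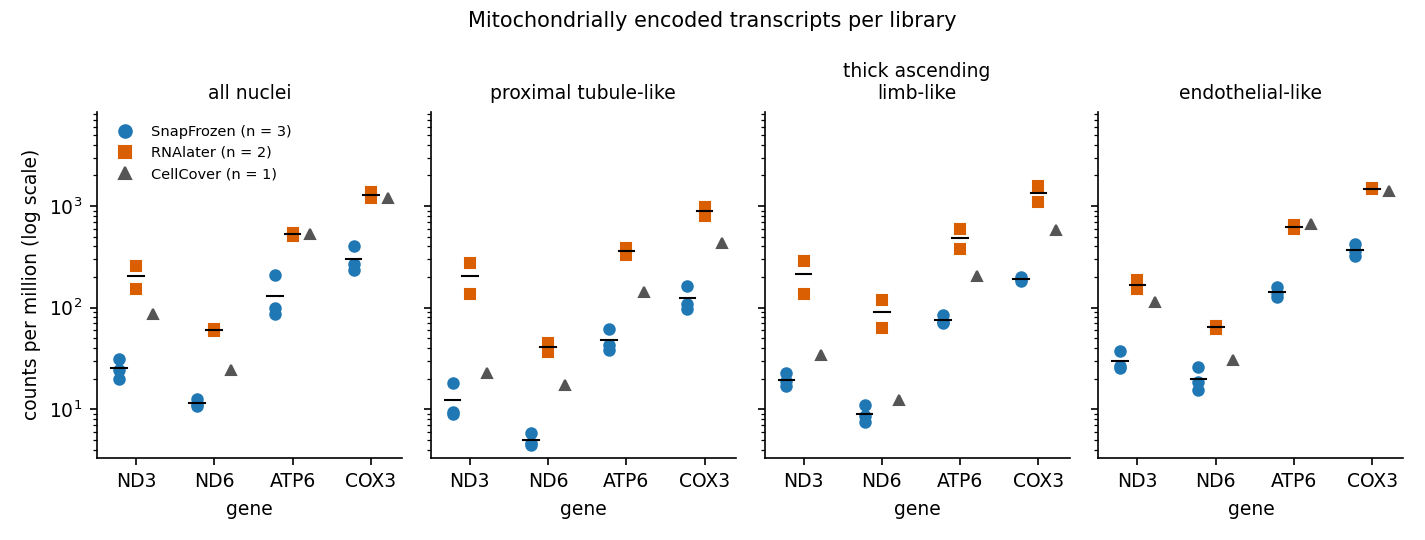
CPM (y axis, log scale) of 4 mitochondrially encoded genes in all nuclei and in 3 classes, a point per library and a bar at each mean of the SnapFrozen and RNAlater groups. In proximal tubule-like nuclei ND3 averaged 12.2 in SnapFrozen and 204 in RNAlater, and in each panel both RNAlater libraries lie above all 3 SnapFrozen libraries.

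In the CellCover library, proximal tubule-like nuclei held far more RNA of a phosphatase and of a sugar-responsive transcription factor. PTPRT rose from 9.29 ± 4.27 CPM (SD, n = 3) to 709.7 CPM (n = 1; log2 6.24 ± 0.54) and MLXIPL, which turns on glycolytic and lipogenic genes (ENSSSCG00000007710, 3: 10898675 to 10934257), from 106 ± 1.78 to 639.7 CPM (2.59 ± 0.22), both with an edgeR adjusted p of 0.0316. Among genes known only by ID, ENSSSCG00000041148 rose from 3.06 ± 1.49 to 100.1 CPM and ENSSSCG00000046752 fell from 39.5 ± 2.01 to 3.20 CPM (both 0.0369). LRP2 had 1879 CPM against 3093 ± 287 (log2 −0.72 ± 0.40, adjusted p = 0.506). EdgeR called 6 genes (5 higher, 1 lower) of 19830, with 2449 at an unadjusted p under 0.05, DESeq2 called 539, and CellCover lay outside the SnapFrozen range for 63.3% of genes. The count was 0 without SnapFrozen replicates 1 or 2, 2 without SnapFrozen replicate 3 (both higher) and 16 without RNAlater replicate 1 (15 higher, 1 lower); the adjusted p of PTPRT then lay between 0.0104 and 0.230 and that of MLXIPL between 0.0272 and 0.230.

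Ribosomal protein genes were lower in 63 of 66 by a median log2 of −1.26 in these nuclei (0 over all genes, 23 adjusted over the list alone, camera adjusted p = 7.33e-18, adjusted p = 0.817 with an estimated correlation), with RPL7A at −1.53 ± 0.45 and RPL31 at −0.45 ± 0.38. Mitochondrially encoded genes were higher in 13 of 13 by a median of 1.59 (0 and 9 adjusted over the list alone, 3.35e-09), and oxidative phosphorylation genes lower in 37 of 44 (median −0.47, 0 and 0 adjusted over the list alone, 0.000184), both with an adjusted p = 0.817 with an estimated correlation. Inflammation (0.0258), immediate early (0.0281; JUN 1.07 ± 0.58) and distal transport genes (0.0258) were higher and cold response genes lower (0.0288), with an adjusted p = 0.817, 0.840, 0.817 and 0.817 with an estimated correlation. The first 3 of these ended without SnapFrozen replicate 3 (0.213, 0.295 and 0.0866) and the last without SnapFrozen replicate 1 (0.164). Markers of the thick ascending limb were higher in 11 of 12 in these nuclei (median 1.04, camera adjusted p = 0.00188; adjusted p = 0.974 with an estimated correlation).

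**Figure D4:**
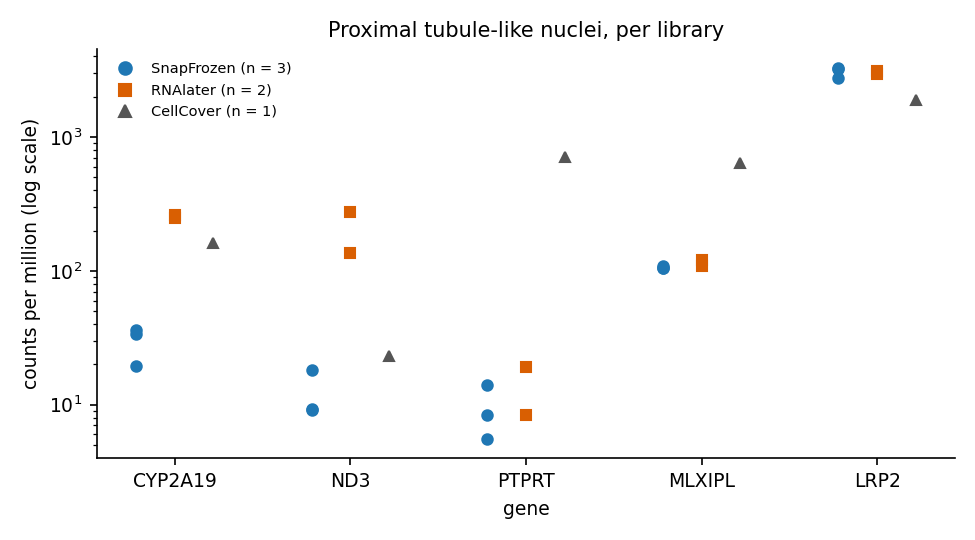
CPM (y axis, log scale) of 5 genes in proximal tubule-like nuclei, a point per library. PTPRT stands at 709.7 in CellCover against a mean of 9.29 in SnapFrozen, and CYP2A19 at a mean of 255 in RNAlater against 29.9, while LRP2 averaged 3023 in RNAlater and 3093 in SnapFrozen.

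In thick ascending limb-like nuclei, 6 mitochondrially encoded transcripts rose in RNAlater. ND3 rose from 19.3 ± 2.89 CPM (SD, n = 3) to 213 ± 109 (n = 2; log2 3.46 ± 0.36), ND6 from 8.999 ± 1.77 to 91.3 ± 39.5 (3.34 ± 0.35) and COX3 from 191 ± 9.95 to 1343 ± 346 (2.81 ± 0.28), all with an edgeR adjusted p of 0.0185. ATP6 (2.68 ± 0.28), cytochrome b, CYTB (MT 15342 to 16481; 2.52 ± 0.28), and COX1 (2.54 ± 0.31, 0.0387) rose too. So did ENSSSCG00000044766, from 1.61 ± 0.604 to 52.6 ± 17.5 CPM (5.08 ± 0.42, 0.0163), ENSSSCG00000038719 and ENSSSCG00000037775. UMOD, the class's own product, had 3152 ± 763 CPM against 2654 ± 454 (log2 0.25 ± 0.33). EdgeR called 9 of 14195 genes, all higher in both RNAlater libraries than in any SnapFrozen library, with 963 at an unadjusted p under 0.05; DESeq2 called 76 and 20.6% of genes did not overlap. The count was 7 (6 higher, 1 lower) without SnapFrozen replicate 1, 0 without SnapFrozen replicate 2 or 3 and 100 (82 higher, 18 lower) without RNAlater replicate 1, and the adjusted p of ND3 lay between 0.00935 and 0.184.

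Mitochondrially encoded genes were higher in 13 of 13 in this class by a median log2 of 2.54 (6 over all genes, 13 adjusted over the list alone, camera adjusted p = 3.58e-36; adjusted p = 0.131 with an estimated correlation; fry 0.0260). Ribosomal protein genes were higher in 60 of 65 (median 0.50, 1.28e-16; adjusted p = 0.652 with an estimated correlation) and tubular injury genes in 15 of 15 (median 0.94, 0.000152; adjusted p = 0.405 with an estimated correlation). RPS20 (4: 75762209 to 75763449) had 305 ± 73.9 CPM against 123 ± 29.5, RPL7A a log2 of 0.21 ± 0.43 and DCDC2 0.99 ± 0.47. SPP1, osteopontin (8: 131077786 to 131085334), had 114 ± 133 CPM against 25.8 ± 2.20 and rested on RNAlater replicate 2, without which its log2 was −0.39. Also higher were oxidative phosphorylation (0.00103), heat shock (0.00258; HSP90AA1 0.77 ± 0.29), unfolded protein response (0.0157), hypoxia (0.0188) and sex-linked genes (0.0393), with an adjusted p = 0.792, 0.551, 0.468, 0.652 and 0.652 with an estimated correlation. None of these 7 lists had a member past the threshold over all genes, and adjusted over the list alone only the 3 sex-linked genes passed. Each of the last 5 calls ended when single libraries were left out. Without SnapFrozen replicate 3 the adjusted p was 0.0514 for heat shock, 0.169 for hypoxia, and 0.0624 for oxidative phosphorylation and sex-linked genes; without SnapFrozen replicate 2 it was 0.0924 for sex-linked genes and 0.115 for the unfolded protein response. Without RNAlater replicate 1 it was 0.144 for oxidative phosphorylation and 0.123 for the unfolded protein response, and without RNAlater replicate 2 it was 0.598 for hypoxia. The other 13 lists had a camera adjusted p between 0.0673 and 0.843. Thin limb markers were higher in 6 of 6 (0.0177) and endothelial markers lower in 11 of 13 (0.0406, but 0.0844 and 0.175 without SnapFrozen replicates 1 and 2 and 0.363 without RNAlater replicate 2), with an adjusted p = 0.705 with an estimated correlation for both.

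Thick ascending limb-like nuclei of the CellCover library had high levels of stress-induced transcription factors. JUN had 123 CPM against 15.5 ± 2.60 (SD, n = 3; log2 2.98 ± 0.32), ATF3 166 against 7.27 ± 3.92 and FOS 27.8 against 6.12 ± 3.50. HERPUD1, a component of protein degradation at the endoplasmic reticulum (6: 18901171 to 18913427), had 355 CPM against 77.7 ± 11.08 (2.20 ± 0.28). The highest fold changes were those of NEK10 (234.8 against 3.02 ± 2.52 CPM), RANBP3L (16: 21562907 to 21612389; 64.7 against 1.34 ± 1.13) and TMEM163 (15: 17260885 to 17548920; 28.9 against 1.10 ± 0.858); the lowest were those of PVALB (5: 10953559 to 10973300), a marker of the distal convoluted tubule (0.340 against 21.3 ± 17.6), DNAH14 (10: 13048002 to 13389497; 1.02 against 19.5 ± 26.8) and GPRC6A (1: 44852731 to 44875518; 0.679 against 11.6 ± 4.73). No gene passed: edgeR called 0 of 14195 with a lowest adjusted p of 0.0921 (JUN), 1754 had an unadjusted p under 0.05, DESeq2 called 200 and 62.0% of genes lay outside the SnapFrozen range. The smaller of the 2 clusters of this class held 17.6%, 5.33% and 15.2% of it in SnapFrozen, 6.59% and 1.27% in RNAlater and 2.42% in CellCover, and no test separated this from differences within nuclei. EdgeR called 70 without RNAlater replicate 1 (65 higher, 5 lower) and 28 without RNAlater replicate 2 (26 and 2).

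In this class 6 lists passed, each with 0 members over all genes. Immediate early genes were higher in 20 of 22 (median log2 1.89, 11 adjusted over the list alone, camera adjusted p = 3.56e-10, adjusted p = 0.428 with an estimated correlation), with IER3 at 0.70 ± 0.27. Unfolded protein response genes were higher in 14 of 16 (median 1.07, 10 adjusted over the list alone, 9.74e-10; fry 0.0340), heat shock chaperones in 17 of 18 (0.78, 6, 1.56e-07; HSP90AA1 1.12 ± 0.35), inflammation genes in 12 of 17 (1.35, 9, 1.3e-05; STAT3 1.66 ± 0.32) and mitochondrially encoded genes in 13 of 13 (1.35, 5, 1.36e-08), where the second value is again the number adjusted over the list alone. In that order the adjusted p = 0.165, 0.241, 0.241 and 0.259 with an estimated correlation. Ribosomal protein genes were lower in 62 of 65 (−0.95, 13 adjusted over the list alone, 6.56e-18, adjusted p = 0.499 with an estimated correlation), with RPL7A at −1.31 ± 0.59 and RPS20 at −0.86 ± 0.39. No single library ended any of these calls. The other 15 lists had a camera adjusted p between 0.0840 and 0.987. Proximal tubule markers were lower in 17 of 17 (median −0.89, 0.00694, but 0.172 without SnapFrozen replicate 1) and distal convoluted tubule markers in 9 of 9 (−1.50, 0.0133), with an adjusted p = 0.875 with an estimated correlation for both.

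Endothelial-like nuclei in RNAlater gained the same kind of transcript. ND3 rose from 29.7 ± 6.64 CPM (SD, n = 3) to 168 ± 23.5 (n = 2; log2 2.50 ± 0.25, edgeR adjusted p = 0.0175), ATP6 from 143 ± 16.7 to 623 ± 33.6 (2.13 ± 0.23, 0.0266) and COX3 from 367 ± 49.8 to 1478 ± 13.5 (2.01 ± 0.26, 0.0484). NRG3, a ligand of ERBB receptors (ENSSSCG00000010344, 14: 83316962 to 84405347), rose from 6.38 ± 1.42 to 36.4 ± 1.37 CPM (2.49 ± 0.30, 0.0327) and the synaptic adhesion gene NRXN3 (ENSSSCG00000028942, 7: 101132780 to 102779809) from 14.4 ± 2.58 to 59.9 ± 10.4 (2.04 ± 0.27, 0.0484). ENSSSCG00000038719 and ENSSSCG00000037775 rose (7.31 ± 0.73 and 5.60 ± 0.67). A copy of the U4 spliceosomal RNA (ENSSSCG00000037051) fell from 19.6 ± 2.56 to 0.277 ± 0.391 CPM and ENSSSCG00000016868 from 155 ± 6.03 to 20.1 ± 4.15 (−2.94 ± 0.26, 0.0163). NRG3 is also a leading gene of an unnamed cluster. Its call ended with any of 4 of the 6 libraries left out and that of NRXN3 with any of 5 (adjusted p up to 0.277 for both), while the adjusted p of ND3 lay between 0.0233 and 0.0885. EdgeR called 9 of 14563 genes (7 higher, 2 lower, without overlap between the groups), with 1823 at an unadjusted p under 0.05, DESeq2 called 173 and 30.5% of genes did not overlap. The count was 5 and 2 without SnapFrozen replicates 2 and 3 (1 lower in each), 71 without RNAlater replicate 1 (69 higher, 2 lower) and 0 without RNAlater replicate 2.

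Of the lists, mitochondrially encoded genes were higher in 13 of 13 in endothelial-like nuclei (median log2 1.74, 3 over all genes and 12 adjusted over the list alone, camera adjusted p = 2.81e-19; adjusted p = 0.165 with an estimated correlation; fry 0.0207). Cold response and splicing genes were lower in 22 of 22 (median −0.39, 0 and 2 adjusted over the list alone, 1.68e-06; adjusted p = 0.3499 with an estimated correlation); DDX5 had 358 ± 126 CPM against 810.2 ± 82.3 (adjusted p = 0.175) and DDX17 363 ± 89.6 against 459 ± 5.15. Extracellular matrix (16 of 21, median 1.04, 9 adjusted over the list alone, 4.58e-05) and distal transport genes (19 of 23, median 0.63, 5 adjusted over the list alone, 0.000602) were higher, again with an adjusted p = 0.3499 with an estimated correlation and with 0 members over all genes; UMOD had 397 ± 55.2 CPM against 134 ± 85.3 (adjusted p = 0.246). Ribosomal protein (3.6e-06), tubular injury (0.00435), oxidative phosphorylation (0.0103), proximal transport (0.0126), hypoxia (0.0126) and sex-linked genes (0.0357) passed as higher, with an adjusted p = 0.734, 0.468, 0.734, 0.734, 0.541 and 0.677 with an estimated correlation. Of the tubular injury genes VIM was at 0.77 ± 0.22 and ANXA2 at 0.02 ± 0.30. Without SnapFrozen replicate 3 the adjusted p was 0.0673 for ribosomal protein, hypoxia and sex-linked genes, 0.0544 for tubular injury, 0.460 for oxidative phosphorylation and 0.0902 for proximal transport. Without SnapFrozen replicate 2 it was 0.317 for proximal transport and 0.0629 for sex-linked genes. Without RNAlater replicate 1 it was 0.0954 for distal transport, 0.0953 for ribosomal protein genes, 0.821 for oxidative phosphorylation and 0.428 for proximal transport, and without RNAlater replicate 2 0.360 for hypoxia. The other 11 lists had a camera adjusted p between 0.0651 and 0.970.

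Markers of 9 other cell types were higher in RNAlater endothelial-like nuclei and those of endothelium lower. Thick ascending limb markers were higher in 11 of 12 (median log2 1.21, camera adjusted p = 7.51e-06), fibroblast markers in 9 of 9 (1.36, 8.6e-06), myeloid markers in 8 of 8 (1.68, 1.22e-05) and T and NK lymphocyte markers in 6 of 6 (1.14, 0.00204), and endothelial markers were lower in 12 of 14 (−0.40, 0.0078). For these the adjusted p = 0.138, 0.167, 0.138, 0.138 and 0.147 with an estimated correlation. Fry called 7 of the 17 marker lists tested in this class, among them the thick ascending limb (fry 0.00104). B and plasma cell and parietal markers were higher too (0.00173 for both; adjusted p = 0.138 with an estimated correlation). Another 5 marker lists passed with all libraries and lost the call with at least 1 of them left out: mural (0.0163, up; 0.0712 without SnapFrozen replicate 2), thin limb (0.0195, up; 0.0679 without RNAlater replicate 2), proximal tubule (0.0220, up), connecting tubule (0.0263, down; 0.748 and turned without RNAlater replicate 2) and dividing markers (0.0286, down). In that order the adjusted p = 0.184, 0.167, 0.574, 0.389 and 0.389 with an estimated correlation. The proximal tubule call ended without SnapFrozen replicate 2 (0.829) or 3 (0.0754) or RNAlater replicate 1 (0.365), and the dividing call without SnapFrozen replicate 2 (0.0978) or 3 (0.110) or RNAlater replicate 1 (0.333). The endothelial-like class is made of several clusters, and the 1 with the fewest UMIs per nucleus (a median of 0.206 of the library median) held 25.2% and 25.5% of the class in RNAlater, 22.0% in CellCover and 9.03%, 7.86% and 9.81% in SnapFrozen.

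Endothelial-like nuclei of the CellCover library had 431 CPM of CA10, a carbonic anhydrase-related protein (12: 27979321 to 28619022), against 12.9 ± 6.77 (SD, n = 3), and DKK2, a Wnt antagonist (8: 114862056 to 114974327), at 12.4 against 0.470 ± 0.222. Of the chaperones, HSPH1 had 707 CPM against 161 ± 38.8 and HSP90AA1 769.6 against 285 ± 98.9. The iron storage gene FTL (6: 54231121 to 54232756) had 99.6 CPM against 528 ± 209.8 (log2 −2.40 ± 0.50) and GPX3 164 against 749 ± 405. The urea transporter SLC14A1 (1: 95354848 to 95381492), which leads 1 of the clusters of this class, had the highest fold change (43.1 against 0.226 ± 0.392 CPM), and CYP24A1, NPSR1 (18: 38942499 to 39212791) and HBB the lowest, with 1.21, 7.89 and 2.43 CPM against 24.7 ± 34.1, 127 ± 99.1 and 28.1 ± 32.7. None passed: edgeR called 0 of 14563 with a lowest adjusted p of 0.103 (CA10 and DKK2), 1435 had an unadjusted p under 0.05, DESeq2 called 118 and 57.6% of genes lay outside the SnapFrozen range. EdgeR called 19 without RNAlater replicate 1 and 2 without RNAlater replicate 2.

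Mitochondrially encoded genes were higher in 13 of 13 in this contrast (median log2 1.75, 0 over all genes and 10 adjusted over the list alone, camera adjusted p = 3.8e-16; adjusted p = 0.213 with an estimated correlation; fry 0.0467). Oxidative phosphorylation genes were lower in 40 of 44 (median −0.71, 8.91e-11) and ribosomal protein genes in 52 of 66 (−0.51, 1.11e-07), while immediate early genes (24 of 27, 1.04, 8.54e-07; JUN 1.60 ± 0.43, DUSP1 1.04 ± 0.58) and heat shock chaperones (17 of 20, 0.74, 1.69e-06) were higher. In that order the adjusted p = 0.569, 0.683, 0.569 and 0.569 with an estimated correlation. Of these 4 lists only heat shock had members that passed adjusted over the list alone, 5 of 20, and none had 1 over all genes. Extracellular matrix (0.00285) and tubular injury genes (0.00746) were higher, and fatty acid oxidation (0.00253), oxidative stress (0.0301) and gluconeogenesis genes (0.0433) lower, with an adjusted p = 0.569, 0.569, 0.683, 0.618 and 0.683 with an estimated correlation. Without SnapFrozen replicate 1 the camera adjusted p was 0.136 for fatty acid oxidation, 0.548 for gluconeogenesis and 0.0670 for oxidative stress. Without SnapFrozen replicate 3 it was 0.108 for tubular injury, without RNAlater replicate 1 0.0815 for gluconeogenesis and 0.0640 for oxidative stress, and without RNAlater replicate 2 0.0603 for gluconeogenesis. The other 11 lists had a camera adjusted p between 0.0748 and 0.995. Thick ascending limb markers were higher in 10 of 12 here (median 1.28, camera adjusted p = 0.000185; adjusted p = 0.331 with an estimated correlation; fry 0.0215) and proximal tubule markers lower in 16 of 17 (−1.09, 0.000185; adjusted p = 0.473 with an estimated correlation). Fry called 3 of the 17 marker lists in this contrast. Thin limb (camera 0.0109) and parietal markers (camera 0.0145) were higher, both with an adjusted p = 0.331 with an estimated correlation. Connecting tubule (0.0340), dividing and endothelial markers were lower and fibroblast and mural markers higher (0.0359 for the last 4), with an adjusted p = 0.473, 0.473, 0.361, 0.473 and 0.432 with an estimated correlation. Without SnapFrozen replicate 1 the adjusted p was 0.117 for endothelial and fibroblast and 0.0641 for mural markers, without SnapFrozen replicate 2 0.0957 for dividing and mural and 0.0571 for fibroblast markers. Without SnapFrozen replicate 3 it was 0.168 for dividing and 0.0654 for endothelial markers, and without RNAlater replicate 2 0.0608 for mural markers.

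Whether RNAlater acted differently on proximal tubule-like and thick ascending limb-like nuclei was tested directly as an interaction in 17514 genes. EdgeR called 0, with 1375 at an unadjusted p under 0.05 and a lowest adjusted p of 0.206. Without RNAlater replicate 1 it called 165 and without RNAlater replicate 2 it called 3, in each case with 1 RNAlater library assumed to vary like the others.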

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

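The comparison of gene lists between classes, and the tests of low-UMI barcodes and of shares of cell types below, were chosen after the results were seen; the tests of free mitochondrial RNA, gene length and spread between libraries were written before they were run. A difference between classes in the RNAlater effect was marked where both RNAlater libraries moved a list in opposite directions in 2 classes. The list also had to pass camera for RNAlater in a class. The same libraries enter the tests below, so their p-values are not separate support. Some larger differences between proximal tubule-like and thick ascending limb-like nuclei went unmarked. Ribosomal protein genes differed by −0.67 and immediate early genes by −0.70 (camera adjusted p = 9.3e-24 and 0.00017). Their adjusted p = 0.549 with an estimated correlation. Heat shock chaperones differed by a median log2 of −0.41 between proximal tubule-like and thick ascending limb-like nuclei (−0.22 and −0.15 in the former, 0.19 and 0.28 in the latter; camera adjusted p = 2.5e-05, adjusted p = 0.549 with an estimated correlation, fry 0.227). Nuclear-encoded oxidative phosphorylation genes differed by −0.32 between the same classes (−0.042 and −0.13, 0.36 and 0.17; camera adjusted p = 4.7e-07; adjusted p = 0.549 with an estimated correlation). The unfolded protein response differed by −0.46 (−0.11 and −0.22, 0.36 and 0.32; camera adjusted p = 0.00074; adjusted p = 0.549 with an estimated correlation). Between proximal tubule-like and endothelial-like nuclei, oxidative phosphorylation genes differed by −0.33 (−0.042 and −0.13, 0.55 and 0.023, so replicate 2 hardly moved in the latter). Their camera adjusted p = 3.3e-06, and the adjusted p = 0.493 with an estimated correlation. Proximal tubule transporters differed by −0.57 between these classes (−0.11 and −0.051, 0.58 and 0.31). Their camera adjusted p = 0.0016, and the adjusted p = 0.698 with an estimated correlation. As given above, the call of these transporters in endothelial-like nuclei ended when single libraries were left out. Markers of the proximal tubule and of several other cell types were higher in those nuclei as well.

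The first pattern weighed is the higher level of mitochondrially encoded transcripts in both RNAlater libraries. If barcodes with few UMIs or in unnamed clusters carried it, it would shrink among nuclei of named classes with at least 3000 UMIs. The median log2 ratio of mean CPM there, taken without TMM scaling, was 2.38 (SD 0.478 over genes). The edgeR median for all nuclei, with TMM scaling, was 1.88. Though the 2 measures differ in scaling, this speaks against that explanation. Free mitochondrial RNA taken up alike by every droplet would add the same number of UMIs to a nucleus of any class. The highest class excess over the lowest was 1.64 in RNAlater replicate 2 (lower 95% bound 1.38) and 2.21 in replicate 1 (lower bound 1.90). These bounds come from resampling nuclei within each library and do not cover the spread between libraries. Uptake might thus account for a part, and the test leaves this open. Storage is the factor in the design, but the animal behind each library is not given in the sources used here, so no biological explanation was tested.

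The other pattern is lower ribosomal protein and higher immediate early transcripts in the CellCover library. Shares of cell types are an unlikely source, since the middle of the 3 class medians was −0.95 for ribosomal protein genes (−0.90 over all nuclei) and 1.04 for immediate early genes (1.32 over all nuclei). Gene length is not likely to explain the former: 1800 other genes in the same range of length had a median of −0.16. A spread between libraries could explain both in part, as the library farthest from 0 among the other 5 stood at 0.50 for ribosomal protein genes (SnapFrozen replicate 1, CellCover −0.86) and −0.75 for immediate early genes (RNAlater replicate 1, CellCover 1.22). With 1 CellCover library, its storage cannot be told apart from the biopsy it came from.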

How the results depend on the processing

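Among values of called genes, 291 of 325 kept call and direction under other settings and 129 of 276 with 1 library left out; the rest kept direction and lost the call. Where no cause is given, the cause was not tested. In simulated data of this size, with genes drawn independently, edgeR recovered 62% of 4-fold changes for RNAlater and 36% for CellCover over all nuclei. There 200 genes were changed at once, so recovery can be lower where few genes change. Sums thinned to the smallest lowered no count of all nuclei or of the 3 classes in the report by over 1.5 times. With such sums the RNAlater count of distal convoluted tubule-like nuclei went from 10 to 5, however. Numbers of called genes are given first for RNAlater, then CellCover, against SnapFrozen. Without a low-count filter edgeR called 16 and 69 in all nuclei (10 for CellCover against RNAlater), 12 and 14 in proximal tubule-like, 365 and 729 in thick ascending limb-like, and 759 and 645 in endothelial-like nuclei. With DESeq2 these were 233 and 788 (239), 188 and 539, 76 and 200, and 173 and 118. With 10 CPM in 2 libraries the RNAlater counts were 0 in all nuclei, 1 in proximal tubule-like and 4 in endothelial-like nuclei, and the CellCover count in proximal tubule-like nuclei was 2. With only the 2 groups compared, CellCover had 26 (186 against RNAlater), 14, 43 and 2. With mitochondrially encoded genes left out, RNAlater had 0, 0, 3 and 5. Beyond the genes removed this ended the calls of ENSSSCG00000038719 over all nuclei (adjusted p = 0.107), of CYP2A19, ENSSSCG00000038719 (both 0.0527) and ENSSSCG00000037775 (0.109) in proximal tubule-like nuclei and of NRXN3 (0.0706) in endothelial-like nuclei, at log2 fold changes as before. Thinned sums gave 1 for CellCover in endothelial-like nuclei, and a marker score per nucleus gave 27 for RNAlater there and 1 class share. With an estimated correlation 0 lists passed in both contrasts over all nuclei, and with fry 1 and 0.

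Values near 0 turned direction. For RNAlater over all nuclei, JUN was at −0.0079 with every barcode and −0.0018 without unnamed clusters, DDX17 at 0.042 with 10 CPM in 2 libraries and 0.012 with only the 2 groups compared, and B2M at −0.059 without unnamed clusters. LRP2 in proximal tubule-like nuclei was at 0.0057 with 10 CPM in 2 libraries and with thinned sums, and ANXA2 in endothelial-like nuclei at −0.032 with the marker score.

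With each library left out in turn, counts ran over all nuclei from 0 to 40 for RNAlater, 0 to 39 for CellCover and 0 to 9 between them; in proximal tubule-like nuclei 0 to 39 and 0 to 16, in thick ascending limb-like 0 to 100 and 0 to 70, in endothelial-like 0 to 71 and 0 to 19; 0 to 165 for the interaction and 0 to 1 for CellCover class shares. Log2 fold changes for RNAlater over all nuclei ran from −0.29 to 0.31 for JUN, −0.55 to 0.19 for ATF3, −0.55 to 1.35 for DCDC2, −0.61 to 0.26 for CDH2, −0.14 to 0.091 for DDX17, −0.23 to 0.57 for B2M, −0.62 to 0.30 for RPL7A and −0.11 to 0.34 for LRP2. In proximal tubule-like nuclei they ran from −0.81 to 0.14 for JUN, −0.97 to 0.38 for KLF6 and −0.15 to 0.012 for LRP2; in thick ascending limb-like from −0.55 to 0.71 for RPL7A, −0.39 to 3.01 for SPP1 and −0.016 to 0.48 for UMOD; in endothelial-like from −0.27 to 0.30 for ANXA2. The camera adjusted p of immediate early genes over all nuclei ran from 6.0e-12 to 0.529, and that of connecting tubule markers in endothelial-like nuclei from 4.7e-05 to 0.748.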

Other observations

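Among the other 10 classes, tested after the data were seen, fibroblast-like nuclei had the most genes called for RNAlater of the classes in which both RNAlater libraries held 30 nuclei or more; podocyte-like nuclei, with 1 such library, had 64. EdgeR called 31 genes, all higher, and DESeq2 153; the edgeR count was 4 without SnapFrozen replicate 1, 45 without SnapFrozen replicate 2, 3 without SnapFrozen replicate 3, 10 without RNAlater replicate 1 and 13 without RNAlater replicate 2. The cytochrome P450 gene CYP2A19 rose from 26.0 ± 11.2 CPM (SD, n = 3) to 285 ± 18.998 (n = 2; log2 3.48 ± 0.35, edgeR adjusted p = 0.0101), as it did in T and NK lymphocyte-like nuclei (30.3 ± 26.6 to 416 ± 19.3 CPM, 0.00953). The protease inhibitor CST3 rose from 43.8 ± 29.4 to 471 ± 216 CPM (0.0408). The 31 calls held 9 mitochondrially encoded genes, 4 genes of the ribosomal protein list (RPLP0, also called, is outside it) and 7 known only by ID. Among the rest, and chosen after their values were seen, CD74 rose from 157.0 ± 26.8 to 761 ± 269 CPM (0.0382), the immunoglobulin joining chain JCHAIN from 29.0 ± 7.002 to 188 ± 29.2 (0.0126) and the T cell adaptor SKAP1 from 24.0 ± 4.54 to 115 ± 1.98 (0.0251).

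Mitochondrially encoded genes made up most of the RNAlater calls in 3 of the other 10 classes, with 8 of 10 in distal convoluted tubule-like, 5 of 6 in connecting tubule-like and 3 of 3 in dividing nuclei. They were 9 of 31 in fibroblast-like, 2 of 6 in intercalated cell-like, 1 of 5 in T and NK lymphocyte-like, 0 of 2 in myeloid-like and 7 of 64 in podocyte-like nuclei, and mural-like and principal cell-like nuclei had 0 calls. ENSSSCG00000038719 was called in 7 of these classes, ND3, ATP6 and ENSSSCG00000037775 in 6 and COX3 in 5.

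Y-linked transcripts marked RNAlater replicate 2; the test of X-linked copies was chosen after this was seen, and that of a mixture was written before it was run. The genes ZFY, EIF1AY and KDM5D had 149.7, 44.1 and 25.4 CPM there and at most 0.116 CPM in any other library, so reads from X-linked copies are not a likely source. If nuclei of a male and a female animal had been mixed, a part of the nuclei would lack these transcripts. Of the 10% of nuclei with the most UMIs, 94.6% (95% interval 92.7 to 96.0%) held at least 1 such UMI, which could still leave room for a small share from another animal. The sources used here give no animal or sex for any library. This library holds nuclei of a male animal, which no other library shows, so the RNAlater contrasts do not separate storage from animal.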
